A study of Mus musculus with 4 samples.

How the data were processed

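Gene expression was measured on Illumina BeadChips in pancreatic islets, the endocrine cell clusters of the pancreas, from C57BL/6 mice with loxP-flanked (floxed) alleles of the nuclear receptor ERRγ, encoded by Esrrg. Islets were infected with an adenovirus carrying EGFP, a fluorescent protein that served as the control, or with one carrying Cre recombinase, which deletes floxed DNA. Per the labels' protocols, total RNA was isolated with Trizol, purified on RNeasy columns with DNase I, and labelled as biotinylated cRNA with the Ambion MessageAmp kit. The 4 arrays fell into 2 groups of 2, called Ad-EGFP and Ad-Cre here. The labels call the 2 arrays of a group technical replicates, so each group was taken as 1 islet preparation. All p-values therefore measure the technical spread between arrays, and the comparison is one between these preparations. Whether the repeated step was RNA labelling, hybridization or something earlier is not given in the sources used here.

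The deposited table of probe intensity values gives, per the file headers, the mean bead signal of each probe on each array, on a linear scale and without normalization. It also gives a detection p-value per probe and array, which the authors deposited from Illumina's software; GenomeStudio is named in the submitters' processing notes, with no version. Bead numbers and bead standard errors stood beside each signal. No signal was below 0, the lowest being 71.8. The authors also deposited processed intensity values of the same 4 arrays. These ranked the probes of each array exactly as the raw signals did (Spearman 1 on every array), with array medians of 181.34, 181.50, 181.27 and 181.39, so they were on a linear scale, not centred, and in the same direction. The method behind them is not given in the sources used here. No genome build was named, and no coordinates are given.

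The table held 25697 probes. The platform annotation gave 1 gene symbol for 23978 of them, several for 0 and none for 1719. Symbols were checked by gene ID against the RefSeq gene table of assembly GRCm38.p6, which matched 23962 named probes, left 16 unmatched under their annotated name, and changed 0 symbols. The 23978 named probes stood for 16593 genes.

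Values were computed in R 4.3.3 with limma 3.58.1; plots were drawn in Python 3.11.15 with matplotlib 3.10.9. Signals were corrected and normalized with limma's neqc, which fits a normal-exponential model with the background mean and SD inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was kept when its detection p was under 0.05 on both arrays of at least 1 group. A gene was represented by its kept probe with the highest mean over the 4 arrays, which left 9265 genes to test, of which 2420 had more than 1 kept probe. Of the called genes with more than 1 kept probe, 45 of 293 had a kept probe of the opposite sign. Groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all 9265 genes. The fit had 2 residual degrees of freedom, 4.92 with those of the prior. A gene was called higher or lower when its adjusted p was under 0.05 and its fold at least 1.5 (0.585 on the log2 scale). Fold changes are Ad-Cre over Ad-EGFP, errors of log2 fold changes are standard errors, and errors of group levels are SDs over 2 arrays.

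Where a gene's probe was not above background on either array of a group, its fold is a lower bound. The bound is the mean log2 value of the other group against the mean, over the dim group's arrays, of the lowest value among probes above background or the probe's own value, whichever was higher. Where 1 array of a group detected the probe, this is stated.

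Gene lists for 30 pathways and cell types, the test, the thresholds, the rule for naming genes and all but 1 of the alternatives were fixed before the data were examined. Each list was described by its members called higher and lower over all genes tested, by the same counts adjusted over the list alone, and by the percentile of its median log2 fold change among 10000 random lists of the same size drawn from the same of 20 expression bins. The percentile describes these arrays and is not a p-value. The named genes were the ERR family; the 12 called genes with the largest rise and the 12 with the largest fall among those detected on all 4 arrays whose groups did not overlap, without clone or predicted names; up to 3 called genes per direction detected in 1 group; and up to 4 called members of each list, or up to 2 members where none was called. A further 3 lists were composed after the data were seen and appear only in the closing section.

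The procedure was tested on simulated data for 9468 genes, 200 of them changed. All simulated genes had the same relative noise, and a far smaller share changed than the 16.4% called in the data. Changed genes were drawn only from genes whose single probe was detected on all 4 arrays. The recovery and the share of false calls therefore need not carry over to the data. Of genes changed 2-fold, 41 of 67 were called (61.2%), and of those changed 3-fold, 54 of 66 (81.8%), with median estimated folds of 1.92 and 2.88. Of genes changed 1.5-fold, 0 of 67 were called, with a median estimate of 1.47. No changed gene was called in the wrong direction. A first criterion, 80% recovery at 2-fold and at 3-fold, was not met and was replaced, after that result was seen, by criteria on estimated size, direction and false calls. Of 121 simulated calls 26 (21.5%) were unchanged genes, more than the nominal 5%. Of these, 25 were among the 963 unchanged genes not detected on all 4 arrays, and 1 was among the 8306 detected on all 4. The class not detected on all 4 held few or no changed genes by design. The simulation therefore does not tell which share of the calls in that class is false. The excess lies where the filter keeps genes near background that were detected in 1 group, and a filter requiring detection on all 4 arrays was added as an alternative after the data were seen. On the same simulated data and with the same filter, eBayes with trend and robust called 143 changed and 3 unchanged genes, against 95 and 26.

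Alternatives were other background corrections, scaling without quantile normalization, the authors' processed values, other filters on detection, the mean over a gene's probes, other variance models, the replicate number as a block, other thresholds, and leaving out each array in turn.

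Each array detected between 52.0% and 52.8% of probes at a detection p under 0.05, with a median of 34 to 38 beads per probe. The number of arrays, 2 per group, limits the precision.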

Results

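Islets from mice with floxed alleles of the orphan nuclear receptor ERRγ, a regulator of oxidative metabolism genes, were infected with Ad-EGFP as control or with Ad-Cre to delete the receptor, and profiled on 2 arrays per group. The comparison asks which islet genes differ between control and ERRγ-deleted islets, in a study of beta cell maturation. The median signal was 170.95 and 169.07 on the Ad-EGFP arrays and 198.32 and 195.46 on the Ad-Cre arrays, so the Ad-Cre arrays were brighter before normalization. After normalization the arrays of a group correlated across genes at 0.993 (Ad-EGFP) and 0.995 (Ad-Cre), against 0.971 to 0.972 between groups; genes are not independent replicates. Differences between 2 quantile-normalized arrays were also divided by their standard error over beads, for probes detected on both. The spread of these ratios was 1.27 and 1.14 within groups and 2.5 to 2.68 between groups. It is the median absolute deviation scaled to estimate an SD. The arrays of a group are technical replicates of 1 islet preparation, so every p-value below measures technical spread only.

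Esrrg itself was not above background on any of the 4 arrays. Its single probe had signals of 122.6 and 122.4 on the Ad-EGFP arrays and 135.4 and 164.6 on the Ad-Cre arrays, with detection p-values of 0.685, 0.669, 0.694 and 0.204. The probe therefore gives no check of the deletion, and whether it lies in the deleted part is not given in the sources used here. Esrrb was also not above background on any array. Esrra, the related receptor that acts on many of the same mitochondrial genes, rose 2.23-fold, from 8.39 ± 0.17 to 9.54 ± 0.09 on the log2 scale (SD, n = 2 arrays each; limma adjusted p = 0.0070). Of 6 measured ERR family members and coactivators, Esrra rose and Ppargc1a, the coactivator PGC-1α, fell. Ppargc1a was not above background on the Ad-Cre arrays and was at least 1.26-fold lower there.

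The largest rise in Ad-Cre against Ad-EGFP islets was that of the urea cycle enzyme gene Ass1 and the largest fall that of the heat shock gene Hspa1a, among genes detected on all 4 arrays. Ass1 rose 15.2-fold (log2 3.93 ± 0.10) and Hspa1a, encoding the inducible chaperone HSP70, fell 16.8-fold (log2 -4.07 ± 0.10). Both had a limma adjusted p of 0.000571. Markers of the exocrine acinar cell were higher as a group, and markers of mature beta cells, leukocytes and mesenchymal cells were lower. Genes of oxidative phosphorylation showed few calls in either direction.

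In all, 1521 of 9265 genes passed both thresholds, 815 higher and 706 lower in Ad-Cre (53.6% higher). At least 2-fold changes were seen for 283 higher and 166 lower genes, and at least 4-fold changes for 37 and 6. The arrays of the groups did not overlap for any of the 1521 genes, which the thresholds all but fix in advance. Over all genes tested this held for 71.2%, against 33.3% if all 4 arrays were interchangeable. As technical pairs of 2 preparations they are not, so any difference between preparations would raise this share. Of the calls, 439 were genes not detected on all 4 arrays, the class that held 25 of 26 false calls in simulated data, and 1082 were detected on all 4. The simulated changes were placed in detected genes only, so the share of false calls among the 439 is not known. Leaving out either Ad-Cre array left far fewer genes called, in a fit whose residual spread came from the Ad-EGFP arrays alone. Log2 fold changes still correlated with those of the full comparison at 0.974 without the first and 0.973 without the second, across genes. The count also depended on the processing, with 840 genes called with normexp at offset 50. It was 586 without background correction and 589 with the authors' values.

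**Figure D1:**
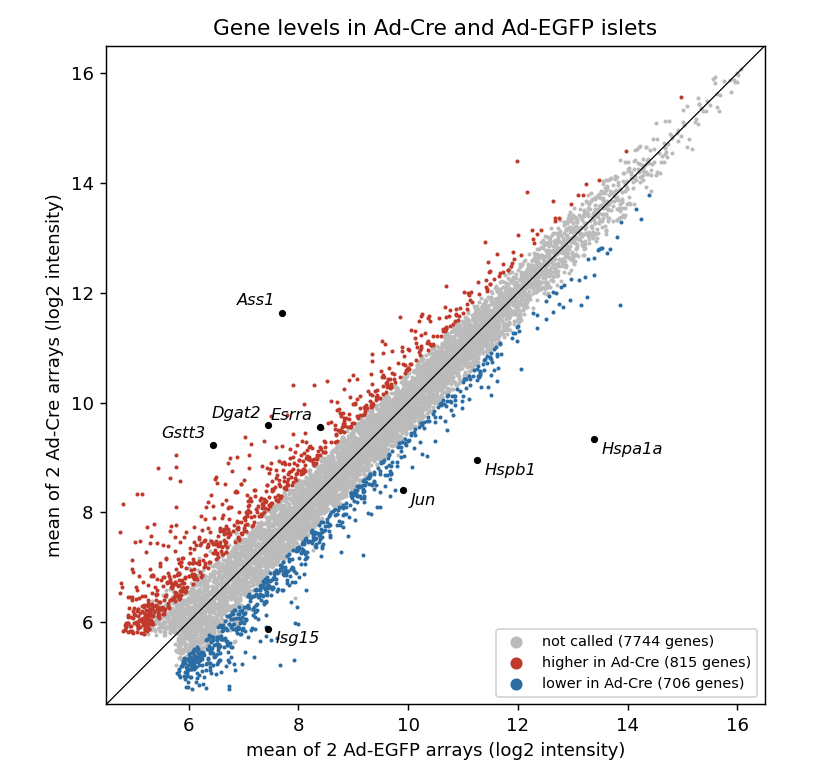
Mean normalized log2 intensity of each gene on the 2 Ad-Cre arrays (vertical) against the 2 Ad-EGFP arrays (horizontal), with 815 genes called higher in red, 706 called lower in blue and the line of equality in black. The empty corner at the lower left comes from the detection filter; Ass1 and Hspa1a lie farthest from the line among the genes named on the plot.

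Among genes detected on all 4 arrays, the largest rises after Ass1 were those of Gstt3, a glutathione transferase (log2 2.79 ± 0.20), Atg9b, an autophagy protein (2.72 ± 0.12), Metrn (2.43 ± 0.10) and Ambp, the precursor of alpha-1-microglobulin and bikunin (2.43 ± 0.09). They were followed by Tesc (2.35), Ramp1, a partner of the calcitonin receptor-like receptor (2.25), the growth factor gene Fgf1 (2.24), Ell3 (2.19), the brush border cadherin Cdhr2 (2.14), the triglyceride synthesis enzyme Dgat2 (2.14) and the neuropeptide gene Gal (2.13). The limma adjusted p of these 11 genes after Ass1 lay between 0.0017 and 0.00552. Cdhr2 had 3 kept probes, with log2 fold changes from 1.31 to 2.14. The Ambp probe stood at 11.99 ± 0.06 in Ad-EGFP and 14.41 ± 0.06 in Ad-Cre.

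The largest falls after Hspa1a were those of 2 further chaperone genes, Hspb1 (log2 -2.31 ± 0.11) and Hsph1 (-2.08 ± 0.08). The interferon-inducible genes Ifi27l2a (-2.03 ± 0.14) and Isg15 (-1.57 ± 0.12) fell, as did Rnd3 (-1.97), Stk35 (-1.70), the protease Ctse (-1.55), Apod (-1.51), the transcription factor genes Jun (-1.50) and Foxq1 (-1.50), and Inhba, the activin beta A subunit (-1.50). The limma adjusted p of these 11 genes lay between 0.00177 and 0.00485. The Hspa1a probe stood at 13.40 ± 0.11 on the Ad-EGFP arrays and 9.33 on the Ad-Cre arrays. The HSP70 genes Hspa1a and Hspa1b are near-identical, so the Hspa1a probe may take signal from both.

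Some genes were above background in 1 group alone. In Ad-Cre islets, Serpina1b was at least 8.45-fold higher, Plet1 at least 6.06-fold and Serpina1d at least 6.04-fold. The alpha-1 antitrypsin genes Serpina1a to Serpina1e are close paralogs, and their probes may not tell them apart. In Ad-EGFP islets, Ulk4 was at least 4.52-fold higher than in Ad-Cre, Ptpn14 at least 3.79-fold and the casein gene Csn3 at least 3.36-fold.

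**Figure D2:**
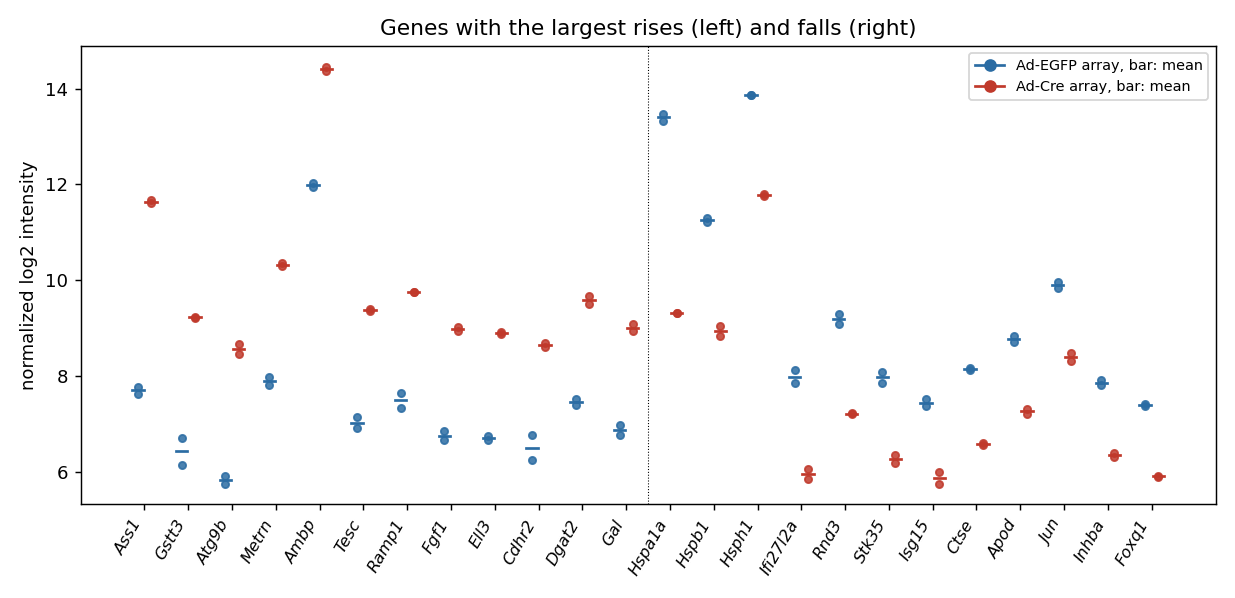
Normalized log2 intensity (vertical) of the 12 genes with the largest rise and the 12 with the largest fall that were detected on all 4 arrays; points are arrays, bars are means of 2. The genes were chosen for large changes and groups that did not overlap, so their separation is no finding; Ass1 had means of 7.71 and 11.64, and Gstt3 and Cdhr2 had the widest Ad-EGFP spread, with SDs of 0.40 and 0.37.

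Markers of the mature beta cell were lower by a small amount in Ad-Cre. Of 22 measured members, 18 had a negative log2 fold change, and the median of -0.32 lay below every one of the random lists (percentile 0). Ucn3, a peptide made by mature beta cells, fell 1.74-fold, the transcription factor gene Nkx6-1 fell 1.67-fold, and the fatty acid receptor gene Ffar1 fell by 0.74 on the log2 scale. Iapp, encoding amylin, rose 2.03-fold. The other 18 members were not called; Mafa and Pdx1 had values of 0.11 and -0.01. Ins2 was the brightest probe on every array, so quantile normalization fixes its difference at 0 and it gives no information. The Ffar1 call was lost with other background corrections, at a log2 value of -0.44 without any. Medians were also negative for the immature beta (-0.24), alpha (-0.14) and delta cell lists (-0.42), though inside the central 95% of random lists. That of PP cells was 0.09. A lower level of these genes within beta cells and a smaller share of beta cells cannot be told apart here, and neither was tested.

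The list of immature beta cell and disallowed genes, which are normally repressed in mature beta cells, went both ways, with 3 members higher and 3 lower of 15 and a median of -0.24 (percentile 5.13). Igfbp4, an insulin-like growth factor binding protein, rose (log2 2.11 ± 0.09), as did Neurog3, the transcription factor of endocrine progenitors (1.87 ± 0.09), and the catalase gene Cat (1.70 ± 0.10). Ndrg2 fell, and was at least 1.59-fold lower in Ad-Cre, where it was not above background.

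Of 7 alpha cell markers 1 fell (Dpp10, -0.70) and the list's median was -0.14 (percentile 16.4). Of 5 delta cell markers the regulator Hhex (-1.17) and the ghrelin receptor gene Ghsr (-0.82) fell, with a median of -0.42 (percentile 2.94). Of 5 PP cell markers 0 were called, with a median of 0.09 (percentile 69.7); Aqp3, detected on 1 of 2 Ad-EGFP arrays, had a value of 0.96 and Etv1 of -0.55.

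Acinar cell markers, which encode digestive enzymes and secretory proteins of the exocrine pancreas, were higher in Ad-Cre. Of 18 measured members 11 rose and 0 fell, and the median of 0.96 lay above every random list (percentile 100). The largest rises were those of Reg2 (2.13), the lipase Cel (2.01, above background on 1 of 2 Ad-EGFP arrays), the carboxypeptidase Cpb1 (1.84) and the chymotrypsin-like Ctrl (1.32). Acinar genes did not move alike: Ctrb1, Try4 and Prss2 had values of -0.36, -0.39 and -0.02 and were not called. Trypsinogen and amylase genes have close paralogs that their probes may not tell apart. Most acinar calls were lost without either Ad-Cre array, as were most calls over all genes. The median was then 0.95 (without the first) and 0.90 (without the second). Duct cell markers had a median of 0.41 (percentile 99.6); of 10 members Ambp and the keratin gene Krt8 (0.84) rose and Lcn2 (-0.80) fell. The duct median was 0.23 without background correction and with the authors' values, and 0.26 without the first Ad-EGFP array.

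Markers of leukocytes and of mesenchymal cells were lower. Of 16 leukocyte markers 6 fell and 0 rose, with a median of -0.49 (percentile 0), among them the Fc receptor chain Fcer1g (-0.89), Laptm5 (-0.79), the lysozyme gene Lyz2 (-0.74) and the complement gene C1qa (-0.68). Of 17 mesenchymal and stellate cell markers 8 fell and 0 rose, with a median of -0.51 (percentile 0.005), among them Vim (-1.07), the collagen gene Col6a2 (from 7.84 to 6.84), Mgp (-0.95) and Timp1 (-0.90). Without either one of the Ad-Cre arrays the calls in both lists were lost, as most were over all genes. The leukocyte median was then -0.43 (without the first) and -0.52 (without the second), and the mesenchymal median -0.64 and -0.54. The count of leukocyte markers called lower was 3 without the second Ad-EGFP array (median -0.41), with median scaling (-0.40), with the authors' values (-0.40) and with no detection filter (-0.40). Endothelial markers had a median of -0.07 (percentile 34.5); of 11 members Eng (-0.93) fell, Tek fell to below background (at least 1.59-fold lower) and Plvap rose (0.60). The 3 measured sex-linked genes had 0 calls, with Uty at -0.34, Kdm5d at -0.33 and a median of -0.33 (percentile 11.3).

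Genes of mitochondrial energy metabolism changed little as groups. Of 33 complex I members 1 rose (Ndufab1, 0.63) and 1 fell (Ndufb11, -1.12, above background on 1 of 2 Ad-Cre arrays), with a median of 0.06 (percentile 77.0). Of 22 members of complexes II to IV 0 were called, with Cox6c at 0.50 and Uqcrb at -0.40 and a median of 0.00 (percentile 42.2). Of 15 ATP synthase genes 3 rose and 0 fell: Atp5e (1.22), Atp5a1 (0.91) and Atp5h (0.60), with a median of 0.15 (percentile 92.2). In the TCA cycle and malate shuttle list, Dld (0.65) and Mdh2 (0.64) rose and Gpd2 (-0.71) and Mdh1 (-0.64) fell among 24 genes, with a median of 0.15 (percentile 96.0). Of 61 mitochondrial ribosome genes 7 rose and 1 fell, with a median of 0.07 (percentile 87.7); Mrpl15 (1.10), Mrps35 (0.76) and Mrps23 (0.69) rose and Mrpl1 (-0.82) fell.

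Fatty acid oxidation and PPAR target genes had a median of 0.21 (percentile 98.7). Of 20 members the enzymes and carriers Acaa2 (0.88), Slc25a20 (0.84) and Acadm (0.77) rose, and Pdk4, the kinase that inhibits pyruvate dehydrogenase, fell (-1.34). The list lay inside the central 95% of random lists when the probes of a gene were averaged (median 0.10), with no detection filter (0.17) and against random lists not matched on expression. In glycolysis and glucose sensing 0 of 14 genes were called, with Hk2 at -0.55, Tpi1 at 0.44 and a median of -0.08 (percentile 16.6). In cholesterol and fatty acid synthesis the desaturase gene Scd1 (1.25) rose and Fdps (-0.80) and Srebf2 (-0.61) fell among 20 genes, with a median of -0.10 (percentile 17.1).

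Secretion genes were called in both directions. Of 26 exocytosis genes the active zone gene Pclo (-0.83) and the synaptotagmin genes Syt4 (-0.71) and Syt5 (-0.63) fell and Stx1a (0.61) rose, with a median of 0.01 (percentile 49.6). Of 18 ion channel and calcium handling genes, Fxyd2 was at least 3.26-fold higher and the mitochondrial calcium uniporter gene Mcu at least 1.41-fold higher, both below background on the Ad-EGFP probes used. Atp2b1 fell (-0.89), and the list's median was -0.12 (percentile 11.2).

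Stress and signalling lists were mixed. Unfolded protein response genes had a median of -0.23 (percentile 0.33), with Trib3 (-1.29) and Nupr1 (-1.07) lower and 0 higher of 24. With median scaling that median was -0.14. Hypoxia genes had a median of 0.32 (percentile 99.1), with 4 higher and 3 lower of 14: Egln3 (1.35, above background on 1 of 2 Ad-EGFP arrays) and Pfkfb4 (1.05) rose, and P4ha1 (-0.80) and Pfkfb3 (at least 1.18-fold) fell. That median lay inside the central 95% without the second Ad-Cre array (0.16), without the second Ad-EGFP array (0.19), with no detection filter (0.21) and with averaged probes (0.20). Of 22 p53 response genes 5 rose and 3 fell, with a median of 0.06 (percentile 67.5). The cell cycle inhibitor gene Cdkn1a (1.11), Ccng1 (1.51) and Phlda3 (1.25) rose; Tnfrsf10b fell (-1.35) on its brighter probe, while its other probe had 0.81. Of 19 antioxidant genes 3 rose and 0 fell: the quinone reductase gene Nqo1 (1.99, above background on 1 of 2 Ad-EGFP arrays), Cat and Gsta4 (1.09), with a median of 0.11 (percentile 86.2).

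Of 31 interferon and antiviral genes 5 rose and 5 fell, with a median of 0.03 (percentile 66.5). Oasl1 (1.40) and Ifit2 (0.95) rose, and Isg15 and Bst2 (-1.33) fell. Of 12 NF-kB and cytokine genes Relb (0.89) rose and Nfkbiz (-1.20) and Lcn2 fell, with a median of -0.10 (percentile 29.3). Of 14 immediate early genes 3 rose and 4 fell, with a median of 0.02 (percentile 59.4): Egr1 (1.34) rose, while Jun, Npas4 (-1.68, above background on 1 of 2 Ad-Cre arrays) and Myc (at least 1.43-fold) fell. Of 25 cell cycle genes 1 rose and 3 fell, with a median of -0.09 (percentile 20.7); Ccne1 (1.10, above background on 1 of 2 Ad-EGFP arrays) rose, and Top2a (-1.07, above background on 1 of 2 Ad-Cre arrays), Tk1 (at least 1.39-fold) and Bub1b (at least 1.13-fold) fell. The ERR family and coactivators had a median of 0.25 (percentile 88.6).

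**Figure D3:**
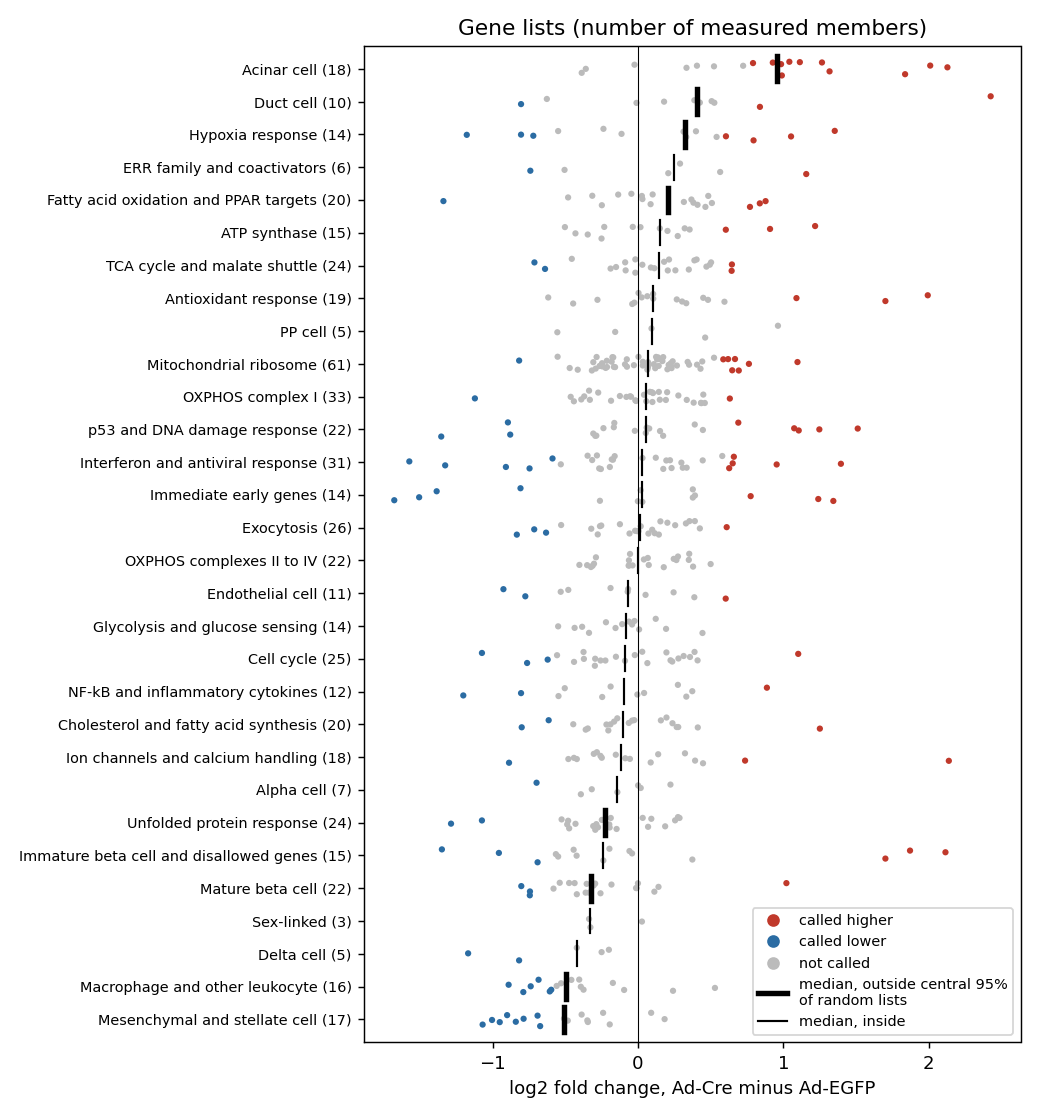
Log2 fold change (Ad-Cre minus Ad-EGFP, horizontal) of each measured member of the 30 lists, sorted by median; red points were called higher, blue lower and grey not called. Thick bars mark the 8 medians outside the central 95% of random lists, from acinar cells at 0.96 to mesenchymal and stellate cells at -0.51; thin bars mark the other medians.

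Over the 30 lists, 4 medians lay above and 4 below the central 95% of random lists. Adjusted over the list alone, the counts were those given above for every list but that of PP cells, where 1 member was then higher. Some called list members had another kept probe under the fold minimum: Lyz2 (-0.21), Mrpl1 (-0.29), Gpd2 (-0.44), Acadm (0.37) and Cdkn1a (0.50). The lists share some genes, such as Cat and Lcn2, so their counts are not independent. With median scaling in place of quantile normalization, 1002 genes were higher and 560 lower (64.1% higher), with a median log2 fold change over all genes of 0.0944.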

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

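All tests of explanations in this part were chosen after the values they bear on had been seen. Probes with no gene name entered no comparison of the report. Of 1719 such probes, 787 were above background in at least 1 group, and 114 of these passed both thresholds of the limma comparison, 46 higher and 68 lower in Ad-Cre. That is 14.5% of those above background, against 16.4% of the named genes tested. No explanation was tested.

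Acinar markers were higher in Ad-Cre, with a median log2 fold change of 0.96 over 18 genes. Background correction and scaling are argued against, since the smallest median under 4 other normalizations was 0.669, above every random list. The 4 are not separate checks. The authors' values (0.67) nearly repeated those without background correction (0.669), and only median scaling (0.992) is known to leave out the quantile step. More acinar tissue in the Ad-Cre preparation stays open: 3 markers (Ctrb1, Try4 and Prss2) had 95% intervals wholly below 0.478, the list's median divided by 2, but the limit of 3 was set when these were known not to have risen, so the test decides nothing. Intervals wholly below 0 were found for 2 of the 18 (binomial p = 0.0734 at 2.5% each). That rate holds for markers that do not change, whereas more acinar tissue would raise every marker. The markers also share the same arrays, so this count decides nothing either. Loss of ERRγ may be the cause but cannot be told apart from any other difference between the preparations, as there was 1 preparation per group.

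Leukocyte and mesenchymal markers were lower in Ad-Cre, with a median of -0.509 over 33 genes. A smaller share of every kind of non-endocrine cell would lower acinar, duct and endothelial markers alike, but the median over 39 of these was higher by 0.914 with a bootstrap standard error of 0.156. That gap comes mainly from acinar (1.46 ± 0.18) and duct markers (0.916 ± 0.21, ± standard error). Endothelial markers, with a median of -0.07 and Eng and Tek lower, were apart by only 0.438 ± 0.215. These errors, like that of 0.156, come from resampling markers. They measure spread between markers on the same arrays and not between preparations. Fewer leukocytes and mesenchymal cells, and a lower level of these genes within the same cells, cannot be told apart: that 23 of the 33 markers had 95% intervals wholly below 0 restates the pattern and goes with both. An effect of ERRγ loss was not tested and stays open.

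Heat shock genes were lower in Ad-Cre, in a list of 19 composed after the falls had been noticed, with 12 called lower, 0 higher and a median of -0.99. Under 4 other normalizations the median nearest to 0 was -0.717, so the fall on these arrays did not hang on these choices. Log2 fold changes under the 4 correlated with the main ones at 0.949 to 0.994 across genes. For a list picked for its falls a low median was therefore all but fixed, and it decides nothing about array processing. The 16 genes left without the 3 largest falls had a median of -0.719. As 18 of the 19 values were negative in a list composed from these data, that outcome was all but fixed. It describes a fall spread over the list and is no test. Less acute stress of all kinds when the Ad-Cre preparation was handled could lower both these and the immediate early genes. The immediate early list had a percentile of 59.4, with Egr1 and Fos higher and Jun and Myc lower, which decides nothing. Handling and ERRγ loss both stay open, since each group was 1 preparation. The groups also differed in what the virus carried, EGFP or Cre, and all 4 arrays were of floxed islets. An effect of EGFP or Cre itself therefore cannot be told apart from ERRγ loss, for this or any other difference between the groups.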

How the results depend on the processing

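The alternative of detection p under 0.05 on all 4 arrays was chosen after seeing the data. It called 1112 genes, 591 higher and 521 lower, of which 1082 were among the 1521. Counts that moved by over 1.5 times were, as all, higher and lower genes: 840, 497 and 343 with normexp at offset 50; 586, 351 and 235 without background correction; 589, 355 and 234 with the authors' values; 955, 495 and 460 with detection p under 0.01 on all 4 arrays; 2728, 1412 and 1316 with no fold minimum; 449, 283 and 166 at 2-fold; and 876, 500 and 376 with treat at 1.2-fold. With no detection filter 440 genes were lower. The cause was not tested, except that stricter filters tested fewer genes and other thresholds change the count by construction. Leaving out 1 array at a time gave 19 to 1524 genes, 15 to 781 higher and 4 to 743 lower, the low ends without the second Ad-Cre array; the remaining array of a group was then assumed to vary like the other group. Without an Ad-Cre array, the residual spread came from the Ad-EGFP arrays alone, with 1 residual degree of freedom.

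The Esrrg probe, below background, had a log2 difference of 0.23, and 0.014 to 0.44 leaving out single arrays. Fatty acid oxidation genes fell inside the central 95% with no detection filter (0.17), averaged probes (0.10) and unmatched random lists (0.21, percentile 97.2), and stayed outside at 0.32 with median scaling and with detection p under 0.01 on all 4 arrays. Hypoxia genes did so with no detection filter (0.21), averaged probes (0.20), without the second Ad-EGFP array (0.19) and without the second Ad-Cre array (0.16), but not without the first Ad-EGFP array (0.40) or the first Ad-Cre array (0.36). The medians of mature beta, acinar, duct, leukocyte, mesenchymal and unfolded protein response lists kept their direction and stayed outside in all 15 alternatives run for them. Of these medians, 2 moved by over 1.5 times: duct to 0.23 without background correction, 0.23 with the authors' values and 0.26 without the first Ad-EGFP array, and unfolded protein response to -0.14 with median scaling. Acinar genes called higher were 7 with detection p under 0.01 on all 4 arrays and 7 at 2-fold, and 0 to 12 leaving out single arrays. Mesenchymal genes called lower were 2 at 2-fold, and 0 to 9 leaving out single arrays. Leukocyte genes called lower were 3 with median scaling, the authors' values, no detection filter or treat, 11 with no fold minimum, 0 at 2-fold, and 0 to 4 leaving out single arrays. Of the 30 genes named for the largest changes, 18 were tested and called with detection p under 0.01 on all 4 arrays, and 12 to 30 leaving out single arrays.

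Over 119 named genes and 14 alternatives, 1297 of 1610 pairs kept their call, 307 lost it, 6 gained it and 0 called genes reversed. Pairs in which the gene was not tested were left out. With detection required on all 4 arrays, 86 of the 119 were tested at a p under 0.01 and 96 at 0.05. The replicate block called 1450 genes, 766 higher and 684 lower. Same-numbered arrays deviated from their group means with a correlation of 0.0155 across genes, so the numbers were not taken to pair the arrays, and with 2 arrays per group no more can be said. A slide block was not run, because no slide is named. Dim genes are the least certain, since 439 of the calls were not detected on all 4 arrays.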

Other observations

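The gene lists of this part were composed after the data were seen, so their counts describe and do not test. Of 14 measured genes in a list of secreted proteins made mostly by liver, 7 were called higher in Ad-Cre and 1 lower. Of the 7, 4 were Serpina1 paralogs, whose probes may not tell them apart, so the count may stand for fewer genes. The higher genes were Serpina1e (at least 1.86-fold), Serpina1c (at least 1.62-fold), the apolipoprotein genes Apoc3 (at least 1.41-fold) and Apoa1 (at least 1.39-fold), with Serpina1b, Serpina1d and Ambp named above. Apoa2 fell (-0.61). Ttr and Rbp4, which islet cells also express, had values of 0.00 and -0.25.

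Of 8 measured genes in a list known from intestinal and mucus-secreting epithelium, 5 were called higher and 0 lower. Tff3, a trefoil peptide above background on 1 of 2 Ad-EGFP arrays, rose by 3.06 on the log2 scale. The guanylin genes Guca2b and Guca2a, not above background in Ad-EGFP, were at least 3.77-fold and 3.36-fold higher. Vil1 and Tff2 had values of 0.14 and 0.71 and were not called.

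Among the heat shock genes, Dnajb1 (-1.33), Dnaja1 (-1.29), Ahsa1 (-1.06) and Hspe1 (-1.01) fell with those named in the report. Hsp90aa1 had a value of 0.01 and Hspa8 of -0.23, and neither was called.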
